A study of Brugia malayi
Wolbachia endosymbiont of Brugia malayi with 21 samples.

How the data were processed

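MicroRNA reads were counted in 21 small-RNA libraries of the filarial nematode Brugia malayi, strain FR3, taken from its mosquito vector (Aedes aegypti, black-eyed Liverpool strain) and from its mammalian host, the jird or Mongolian gerbil (Meriones unguiculatus). Groups were taken from the labels: vector at 18 hours post infection (hpi), 4 days post infection (dpi) and 8 dpi, 2 libraries each; jird at 4 dpi, 1 library; jird at 8 dpi, 2; immature males at 20 dpi, 2; immature females at 24 dpi, 2; adult males, 2; adult females, 4; embryos collected from gravid females, 2. Per the labels' protocols, gerbils were infected in the peritoneal cavity with L3 larvae, and mosquitoes were fed blood that carried microfilariae. The mosquitoes were dissected, but which parts went into the vector libraries is not given in the sources used here. The labels do not say that replicates came from separate animals, so every p-value measures only the spread between these samples, which may be technical.

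The authors deposited raw counts for 284 mature microRNA arms of 160 genes, named by gene with the suffix a or b for the arm. BWA 0.7.12 and HTSeq 0.5.3p9 were used, per the submitters' processing notes, which give neither their roles nor their settings. The deposited TPM table covers 15 libraries, without those from the vector. Recomputing the TPM values from the counts and the deposited arm lengths gave a largest relative difference of 4.92e-15. The authors also deposited an annotation with 260 B. malayi and 182 A. aegypti microRNA genes, mature sequences, predicted target sites in 13902 transcripts, and mRNA TPM values for 5918 genes in 15 libraries with co-expression modules. Of the 182 mosquito genes, 0 are in the count table. The file with the enrichment of terms in the modules gives odds ratios, p-values and corrected p-values from the authors, per the file headers; the test behind them is not given in the sources used here. Coordinates are those of the deposited annotation, whose contig names carry the prefix Bm_v4; a genome sequence was not used here. How the authors treated strand and reads with several matches is not given in the sources used here. In 18 pairs of arms on opposite strands of a locus, counts were equal within 1% in all 18, so reads of the partners cannot be told apart. Partners were counted and tested on their own, so the same reads may enter totals, shares and counts of calls more than once. Whether copies with the same mature sequence share reads was not tested.

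Mature sequences were assigned to arms by identifier or, where an identifier and its locus disagreed, by locus, and were used where the length was within 2 bases. This gave 224 arms a sequence, which hold 90.5% of all counts. Families were formed from the seed, bases 2 to 8 of the mature sequence, and fixed with the other choices before the data were examined: let-7, lin-4, miR-100/miR-51, miR-10, miR-35/miR-36, miR-71, miR-34, miR-2/miR-43, bantam, miR-9, miR-4/miR-79, miR-44/miR-279, miR-31/miR-72, miR-92/miR-235, miR-183/miR-228/miR-263, miR-50/miR-190, miR-252, miR-86, miR-87, miR-200/miR-236, miR-7, miR-1, miR-133, miR-124, miR-993 and miR-184. MicroRNAs of the jird, of the mosquito and of the numbered filarial series had been listed by name only, and the deposited identifiers carry no such names, so those lists were not used.

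Counts were scaled with TMM factors and tested with edgeR 4.0.16 (quasi-likelihood, robust) in R 4.3.3, in a single model of all 21 libraries with a term for each group. Arms were kept with the filterByExpr function (minimum count 10, minimum total 15), which left 135. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Families with at least 2 tested arms were tested with fry from limma 3.58.1, adjusted over families within a comparison; its directional p asks whether the members move, on balance, in a single direction, and its mixed p whether they move in either direction. Expression is given as TMM-scaled CPM, mean ± SD, and log2 changes with their SE from the edgeR model. Because TMM rescales the totals, a scaled level can exceed the total that counts are scaled to. Where a group held 0 counts, the fold is a bound computed against 3 counts over that group; with 1 to 3 counts, the ratio of pooled scaled counts is given with its 95% counting interval. Fitted folds of such arms depend on the prior count and are no bound. Shares of a library's counts carry 95% Wilson intervals. Intervals and bounds cover counting error only, since reads without molecular identifiers are not independent molecules. Bounds and ratios of folds use TMM-scaled totals and were not computed with other scalings.

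The text names a part of the microRNAs that a fixed rule selects, and which of them it names was decided after their values were seen. The rule selects arms with a mean of at least 10 CPM in the higher group, called in the comparison and without overlap between the groups' libraries, up to 12 higher and 12 lower by size of change in the main comparisons (adult females against males, embryos against adult females, jird against vector at 8 dpi, vector at 8 dpi against 18 hpi), up to 4 and 4 in the secondary ones; the 5 most abundant of each stage; every measured family member; and, for predicted targets, the named arms of the main comparisons only. Overlap between libraries was not checked for the interaction of sex and maturity. Each arm counts on its own, also where arms share a mature sequence.

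Alternatives were RLE factors, library size alone, library sizes without the 3 largest microRNAs, no filter, DESeq2 1.42.0, only the libraries compared, arms of the same sequence summed, limma on log2 of the TPM with a pseudocount of 1 or 10 or a minimum mean TPM of 10, the replicate letter as a block, and each library left out in turn. The 3 largest microRNAs were those with the most counts over all libraries together. In the vector libraries they held 7.53% to 16.0% of counts, and the largest there, miR-34, stayed in. When a left-out library leaves a group with a single library, that library is assumed to vary like those of other groups. Chosen after seeing the data were: keeping a single arm of each opposite-strand pair, leaving out the vector libraries, leaving out microRNAs whose sequence insects share, and a minimum target alignment of 15 bases. The mRNA values carry no statement of their samples' origin and were described without a test, on log2(TPM + 1) scaled to z per gene. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps.

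The edgeR step was tested on simulated data: 10 simulations per comparison of 135 microRNAs, 40 of them changed, with the observed spreads. Depths were set by library sizes multiplied by their TMM factors, so they differ from the observed ones. Both groups of a comparison started from their average profile, which removed differences such as that of miR-34 between jird and vector. Fewer microRNAs also changed than the 80 called between adult females and males in the data. The shares of false calls, with TMM or RLE factors, may therefore not carry over. With changes in both directions at every size, a 4-fold change was called in 82% of cases for adult females against males, 84% for embryos against adult females, 62% for immature females against males, 30% for jird against vector at 8 dpi and 18% for vector at 8 dpi against 18 hpi. The share of calls that were false was 7.16%, 9.30%, 0.803%, 27.4% and 22.7% in the same order. The design written first, in which each size went in a single direction only, gave shares of 4.55%, 6.38%, 1.28%, 39.5% and 36.8%. With RLE factors they were 1.20% and 2.75% for jird against vector in the first and second design, and 12.4% and 11.6% for vector at 8 dpi against 18 hpi. On simulated adult females and males, fry called 30 of 30 shifted families and 4 of 50 unshifted ones. Depth, in counts per library, ran from 1820 to 5348 in the 6 vector libraries and from 21687 to 183394 in the other 15.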

Results

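The libraries followed the microRNAs of B. malayi, a lymphatic filarial worm that carries the bacterium Wolbachia, from larvae in the mosquito to adults and embryos from jirds. MicroRNAs are RNAs of about 22 bases that lower the output of the transcripts they pair with, mainly through the seed near their 5′ end. The 6 vector libraries held 1820 to 5348 counts and showed 45 to 80 of the 284 microRNA arms; the other 15 held 21687 to 183394 counts and showed 134 to 179 arms. The vector values are therefore the least precise. Of 135 arms tested, 127 differed among the 10 groups (edgeR quasi-likelihood F test, Benjamini-Hochberg; 127 at an unadjusted p under the same threshold of 0.05).

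The most abundant microRNA was miR-71 in several stages, but not in adult males or in the vector libraries. In the single library of 4 dpi larvae from jirds, miR-71 (WBGene00235458.a), a regulator of lifespan and stress resistance in Caenorhabditis elegans, took 28.2% of counts (Wilson interval 28.0 to 28.4), and lin-4 (WBGene00255642.a), which times larval development in C. elegans, took 19.7% (19.5 to 19.9). In jird larvae at 8 dpi the most abundant were miR-71 at 399349 ± 158874 CPM and miR-92 (WBGene00255614.a) at 306729 ± 120268 (n = 2). In adult females miR-71 at 63106 ± 8729 and the miR-100/miR-51 member WBGene00255615.a at 59488 ± 12222 led (n = 4), and in embryos the same arms led at 83008 ± 28964 and 64102 ± 7151 (n = 2). In adult males WBGene00255694.a (chromosome 2, 6077376 to 6077397, plus strand, CGAGGTATTGTTTATTGGCTGA), an arm outside the listed families, was the most abundant at 120480 ± 10556 (n = 2). The bantam member WBGene00235433.a and the miR-44/miR-279 member WBGene00235521.a were among the 5 most abundant arms of several stages, but each has an opposite-strand partner with nearly equal counts.

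**Figure D1:**
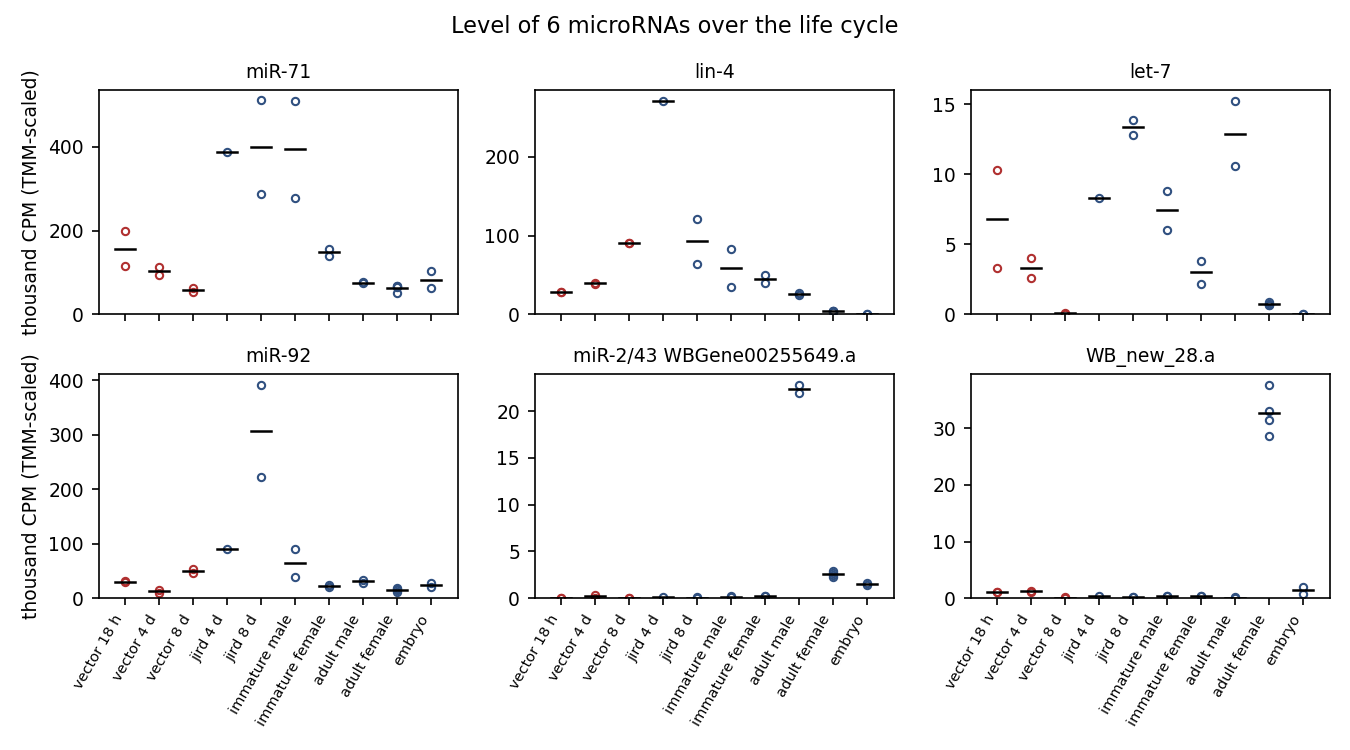
Level of 6 microRNAs in each library (open circles, TMM-scaled CPM in units of 1000) with group means (black bars) over the 10 groups, vector libraries in red and the others in blue. The level of lin-4 reached 270389 CPM in the jird library at 4 dpi and 790.3 ± 329 in embryos, and WB_new_28.a stood at 32737 ± 3791 in adult females.

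Adult females and males were compared to find microRNAs that differ between the sexes of mature worms. Females held far more of WB_new_28.a (X chromosome, 1458020 to 1458042, minus strand, TACTGGCCTTTCAAACTCTGGGA): 32737 ± 3791 CPM in females (n = 4) and 98.0 ± 8.72 in males (n = 2), a log2 difference of 8.35 (SE 0.51, edgeR adjusted p = 5.22e-54). The fry test, which counts each copy on its own, called the miR-2/miR-43 family higher in females (adjusted p = 1.92e-06). Of its 10 tested members 6 were higher, 2 lower and 2 not called (8 called when adjusted over the list alone). The median log2 was 5.94, or 5.42 with members at 0 set to their bound. By share of counts the family as a whole was similar, at 7.22 ± 1.35% in adult females and 6.77 ± 0.68% in adult males, which was not tested. The 6 higher members carry only 2 mature sequences: WBGene00255629.a, WB_new_1.a, WB_new_2.a and WB_new_3.a share CATCACAGACCCGATGCAGCGAC, and WBGene00255634.a and WB_new_10.a share TATCACAGAATTGATGCAGCGAGC. WB_new_2.a stood at 7459 ± 1293 CPM against 65.3 ± 5.81 (log2 6.78, SE 0.56), and WB_new_10.a was at least 32.1-fold higher, with 0 counts in males. Its copy WBGene00255634.a had 1 count in males. Both members of miR-35/miR-36, a family of early embryos in C. elegans, were higher in females (2 called over the list alone, fry adjusted p = 0.000471; median log2 6.09, or 3.97 with bounds): WBGene00255671.b at least 9.96-fold, and WB_new_11.b at a ratio of 28.6 (counting interval 5.01 to 1142).

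Further microRNAs higher in females were miR-7 (WBGene00235395.a; log2 3.13, SE 0.53, 1444 ± 226 against 161 ± 31.7 CPM), the miR-100/miR-51 member WBGene00255697.a (2.45, SE 0.33), the bantam member WB_new_29.a (2.17, SE 0.41), WBGene00255662.a of miR-87 (1.87, SE 0.45), miR-86 (WBGene00235434.a; 1.66, SE 0.33) and WBGene00235393.a of miR-4/miR-79 (ratio 14.1, interval 3.80 to 119). The other miR-4/miR-79 member tested, WB_new_4.b, was lower in females (-1.86, SE 0.67; -2.65 without adult female c), a call that ended without adult male b (-1.55). The family was not called (fry adjusted p = 0.265). WBGene00255629.b, the other arm of a miR-2/miR-43 gene (chromosome 2, 11904721 to 11904741, plus strand, AGTTGTATCGTCTGTGATATG), had 2240 counts in females and 1 in males, a ratio of 704 (126 to 27829). Higher arms lay close together: of 18 arms tested from 11 genes at 11904721 to 11923905 on chromosome 2, 17 were higher and 0 lower, with 11295 counts in females and 72 in males, and all 10 tested arms of the contig Bm_034_hap were higher. The stretch and the contig carry copies of the same sequences, so reads may have been split between them.

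**Figure D2:**
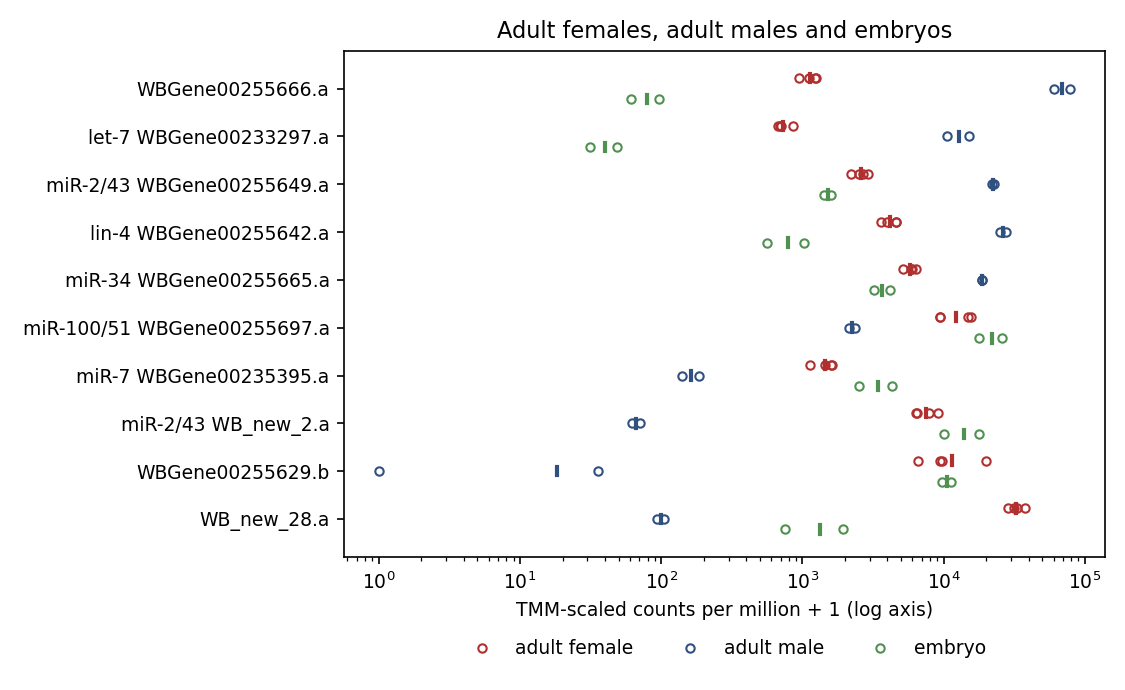
TMM-scaled CPM plus 1 (log axis) of 10 microRNAs in adult females (n = 4), adult males (n = 2) and embryos (n = 2); circles are libraries and bars group means. WBGene00255666.a stood at 1130.2 ± 141 CPM in females and 69413 ± 13099.6 in males, and WB_new_28.a at 32737 ± 3791 and 98.0 ± 8.72.

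**Figure D3:**
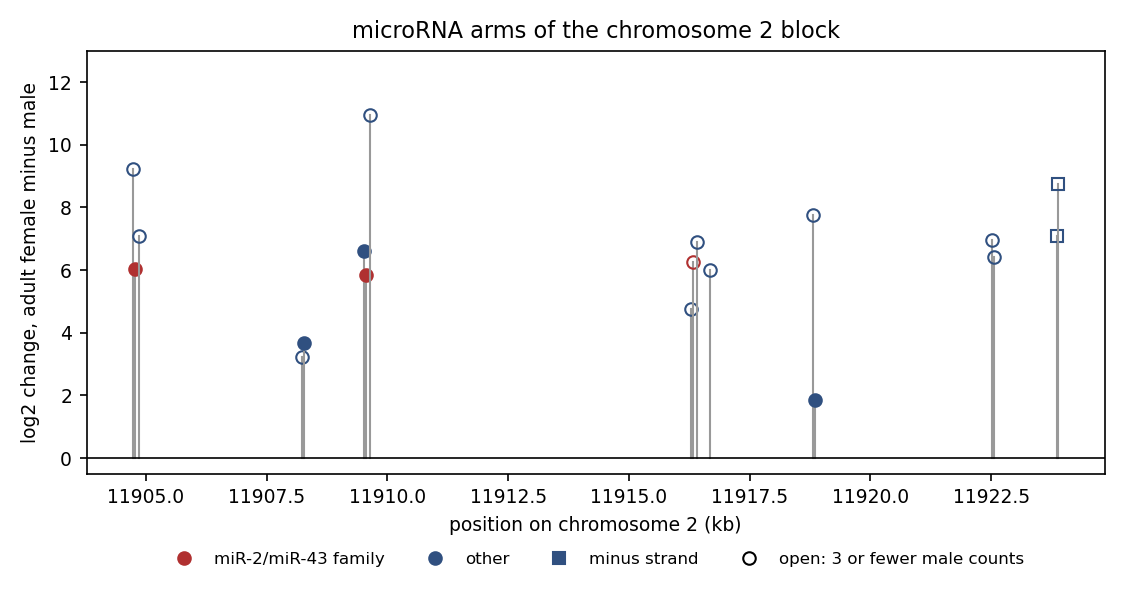
Log2 change, adult females minus males, of the 18 tested arms between 11904721 and 11923905 on chromosome 2, against position in kb; red marks the miR-2/miR-43 family, squares the minus strand and open symbols arms with 3 or fewer male counts, whose fitted change is no bound. Of the 18 arms, 17 were called higher in females.

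Males held more of WBGene00255666.a (chromosome 3, 12845442 to 12845463, minus strand, TGAGTATTTTCGGTTTCGCATC), at 69413 ± 13099.6 CPM against 1130.2 ± 141 in females (log2 -5.94, SE 0.30, edgeR adjusted p = 3.11e-74). Males were also higher in let-7 (WBGene00233297.a), which times the passage to the adult in C. elegans (-4.14, SE 0.31, 12899 ± 3264 against 730.5 ± 82.7 CPM), in lin-4 (-2.65, SE 0.28, 26270.1 ± 1896 against 4184 ± 469) and in miR-34 (WBGene00255665.a; -1.68, SE 0.29, 18672 ± 87.6 against 5820.2 ± 502). The miR-2/miR-43 members WBGene00255649.a (-3.12, SE 0.30) and WBGene00255680.a (-1.58, SE 0.27) went against the rest of their family, as did the miR-100/miR-51 member WBGene00235495.a (-1.98, SE 0.37) in a family with 2 members higher, 1 lower and 1 not called (3 over the list alone, fry mixed adjusted p = 0.0484). Both miR-9 members were called lower in females (WB_new_4.a -0.80, WB_new_5.a -0.74, fry adjusted p = 0.0447), a family call that 5 of the 6 left-out libraries ended (highest adjusted p 0.247, without adult male a) and that did not hold with library size alone (0.0698) or without the 3 largest microRNAs in the library sizes (0.0579). The calls of both members ended without adult male a (WB_new_4.a -0.71, WB_new_5.a -0.58) or adult male b (-0.90 each), and that of WB_new_5.a with library size alone (-0.54) or without adult female c (-0.66). miR-71 (-0.26, adjusted p = 0.425), bantam WBGene00235433.a (0.44, 0.172; called at 0.61 with library size alone) and WBGene00255615.a (-0.27, 0.395) did not pass. In all, 80 arms were called, 49 higher and 31 lower in females (84 at an unadjusted p under 0.05). The calls of miR-92 (-1.01, lower) and WBGene00255698.a (higher) ended without adult male b (-0.89) and adult male a (0.84), respectively, and that of miR-1 (WB_new_27.a; 0.92) without adult female d (0.66) or adult male b (0.74). The low male counts moved WBGene00255629.b to a fitted 12.28 without adult male b and 8.26 without adult male a, and the miR-35/miR-36 median to 7.55 without adult male a. The fitted 4.63 of WB_new_11.b moved to 7.53 without adult male a and 3.81 without adult male b.

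Embryos were compared with the adult females that carry them. Embryos held little WB_new_28.a, at 1340.3 ± 829.8 CPM against 32737 ± 3791 in females (log2 -4.64, SE 0.37, edgeR adjusted p = 3.74e-32; -5.47 without embryo a), and little let-7, with 4 counts against 143 (-4.21, SE 0.58). WBGene00255666.a (-3.88, SE 0.48, 77.7 ± 24.7 CPM), WBGene00255660.a (X chromosome, 3223715 to 3223737, minus strand, TTTGTACTTCGGCTAAGGTGCTG; -3.12, SE 0.35) and lin-4 (-2.43, SE 0.35, 790.3 ± 329 CPM) were lower too. Both miR-9 members were lower (WB_new_5.a -3.04, SE 0.37, and WB_new_4.a -2.68, SE 0.36), and the family was called (2 over the list alone, fry adjusted p = 0.000131). The bantam member WB_new_29.a was lower at -1.31 (SE 0.36), and WBGene00255627.b at least 6.47-fold lower with 0 counts in embryos. In all, 36 arms were called, 16 higher and 20 lower (54 at an unadjusted p under 0.05).

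Higher in embryos were the miR-44/miR-279 member WBGene00255646.a (1.43, SE 0.30, 11022 ± 2884 against 4087 ± 1137 CPM) and WBGene00255700.a of miR-183/miR-228/miR-263 (1.61, SE 0.37). The first call ended without embryo b (0.99) and the second without adult female a (0.98), adult female c, embryo a or embryo b (up to 1.23, adjusted p up to 0.0999). The other higher family members were miR-7 (1.23), miR-50/miR-190 (WBGene00235460.a; 1.11), 4 copies in miR-2/miR-43 (0.90 to 0.96) and the miR-100/miR-51 members WBGene00255698.a (0.86) and WBGene00255697.a (0.83). Each lost its call in at least 5 of the 6 left-out libraries, with adjusted p up to 0.275, 0.249, 0.629, 0.568 and 0.522 in that order. The miR-44/miR-279 family call (fry adjusted p = 0.00539; 1 over the list alone) ended in 5 left-out libraries (highest 0.178, without embryo b), and miR-2/miR-43 was called only in the mixed test (0.0066; 5 over the list alone, median log2 0.13). The miR-35/miR-36 arms WBGene00255671.b (-1.04, adjusted p = 0.118) and WB_new_11.b (-0.82, 0.240) were not called, at 232 ± 8.38 and 263 ± 31.4 CPM in embryos. The first was called without adult female a (-1.57) or adult female b (-1.54), and WB_new_11.b without adult female b (-1.37). WBGene00255629.b stood at 10486 ± 1018 CPM in embryos and 11399 ± 5808 in females (-0.12). With the 3 largest microRNAs left out of the library sizes the split became 5 higher and 29 lower, with a median shift of -0.39. The calls of miR-7 (WBGene00235395.a, 0.79), WBGene00255698.a (0.45), WBGene00255697.a (0.42) and the 4 miR-2/miR-43 copies (WB_new_3.a 0.48, WB_new_1.a 0.46, WBGene00255629.a and WB_new_2.a 0.44 each) ended there, and WBGene00255671.b was called lower (-1.40).

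Larvae at 8 dpi from jirds were set against larvae at 8 dpi in the vector, so host and developmental stage differ together. The vector libraries may also hold mosquito reads, so differences cannot be told apart from those reads either. Jird larvae held less miR-34 (3727 ± 306 against 181700 ± 43546 CPM; log2 -5.61, SE 0.42, edgeR adjusted p = 1.59e-36, n = 2 each), less of the miR-100/miR-51 member WBGene00235495.a (-2.93, SE 0.37, -3.61 without jird 8 dpi b) and less WBGene00235418.a (-5.13, SE 0.60, 34 counts in the vector). They held more WBGene00255694.a (6.42, SE 0.47, 104953 ± 11368 against 1246 ± 1207 CPM), which moved to 5.64 and 8.05 without vector 8 dpi a and b. let-7 had 2355 counts in jird larvae and 1 in vector larvae, a ratio of 198 (35.5 to 7817). Its fitted change of 7.57 is no bound. It moved to 6.81 with RLE factors, 6.64 with library size alone, 12.4 without vector 8 dpi a and 6.64 without vector 8 dpi b. miR-71 (2.77, SE 0.36) and miR-92 (2.61, SE 0.35) were higher as well, and fell to 1.92 and 1.75 without jird 8 dpi b. WBGene00255620.a (chromosome 2, 10830202 to 10830224, plus strand, TGGGTAATCAGGACAGTGCATAT) was at least 5.96-fold higher, with an opposite-strand partner of equal counts (WBGene00255621.a). This bound and the let-7 ratio rest on TMM factors. Both would be lower with library size alone, which shifted fitted changes by a median of -0.91.

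In miR-100/miR-51, 2 members were higher (WBGene00255698.a 1.51, WBGene00255615.a 1.27), 1 lower and 1 not called (WBGene00255697.a 0.29, or -0.49 with RLE factors and -0.65 with library size alone), with a mixed fry adjusted p of 0.0416 (3 over the list alone). Both higher calls ended without jird 8 dpi b (0.98 and 0.64) with RLE factors (0.73 and 0.50) and with library size alone (0.55 and 0.30). miR-86 was lower at -1.85 (SE 0.36) and WBGene00235425.b at -2.37 (SE 0.52), but not when 4 and 8 dpi were averaged in both hosts (-0.27, adjusted p = 0.763, and -0.81, 0.294). miR-1, a muscle microRNA, was lower at -0.98 (ended without jird 8 dpi b, -0.96, or vector 8 dpi b, -0.80). lin-4 (WBGene00255642.a) was not called at 0.03, but stood at -0.73 (adjusted p 0.0655) with RLE factors and was called lower at -0.98 with library size alone, so its direction depends on the scaling. Of the 33 arms called, 25 were higher and 8 lower in jird larvae (47 at an unadjusted p under 0.05), but RLE factors gave 9 higher and 11 lower and library size alone 9 and 12, with median shifts of -0.76 and -0.91; 17 of the 33 calls were kept under each. With library size alone miR-34 (WBGene00255665.a) stood at -6.54, WBGene00235495.a at -3.89, WBGene00235418.a at -6.07, WBGene00255694.a at 5.49, miR-71 (WBGene00235458.a) at 1.78, miR-92 (WBGene00255614.a) at 1.61, miR-86 (WBGene00235434.a) at -2.79, WBGene00235425.b at -3.35 and miR-1 (WB_new_27.a) at -1.83. With RLE factors they stood at -6.39, -3.70, -5.92, 5.64, 2.02, 1.85, -2.63, -3.14 and -1.80 in that order. In simulated libraries, which lack the miR-34 difference between the groups, 27.4% to 39.5% of calls were false with TMM factors. The smaller changes therefore carry little weight.

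**Figure D4:**
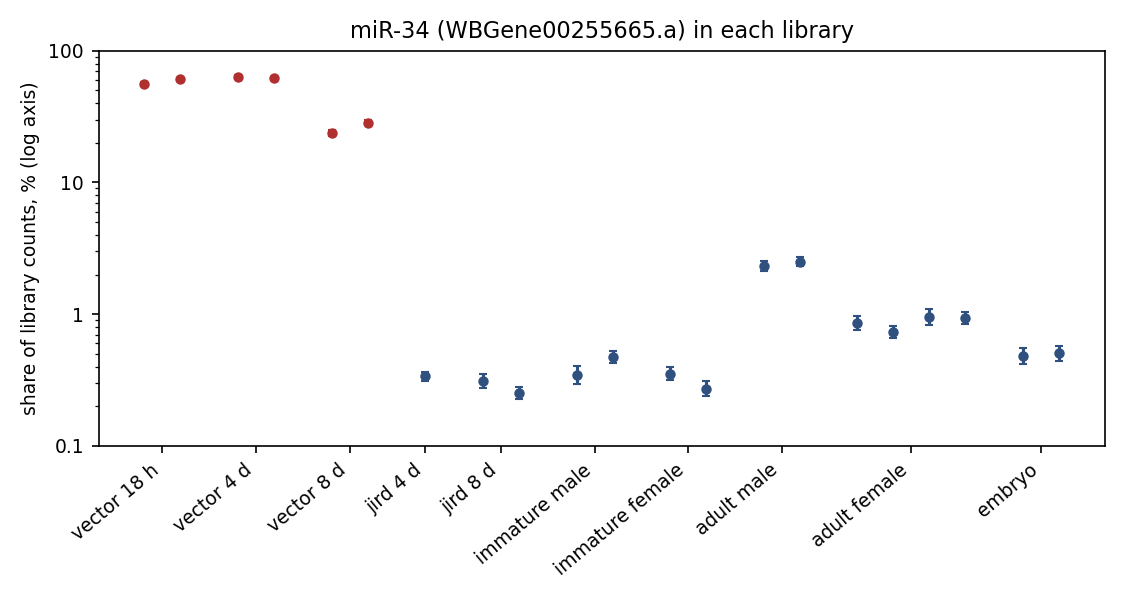
Share of each library's counts taken by miR-34, in percent on a log axis, with 95% Wilson intervals; vector libraries in red, the others in blue. The vector libraries sit between 23.9% and 63.6% and the other 15 between 0.252% and 2.51%.

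Vector libraries may hold mosquito reads, and there is no library of mosquito alone. In every comparison among vector times, changes in the larvae therefore cannot be told apart from changes in the share of mosquito reads. The vector libraries were first compared from 18 hpi to 8 dpi. Over that time miR-34 fell by 3.11 on the log2 scale (SE 0.37, 1571010 ± 639052 to 181700 ± 43546 CPM, n = 2 each, a scaled level that can exceed the total, and -1.16 with library size alone), the miR-100/miR-51 member WBGene00235495.a fell by 4.54 (SE 0.39, -2.61 with library size alone, 212483 ± 71074 to 9154 ± 3683) and both miR-9 members fell (WB_new_4.a -3.35, SE 0.39, and WB_new_5.a -2.86, SE 0.38). By share of counts, miR-34 went from 58.4% to 26.1%. lin-4 rose by 1.66 (SE 0.38, 28618 ± 168 to 90739.6 ± 243 CPM), or by 3.58 with library size alone, and from 1.14% to 13.2% of counts. let-7 went from 13 counts to 1, a ratio of 102 (15.3 to 4327). Its fitted change of -6.61 is no bound. It moved to -4.64 with library size alone, -5.55 without vector 18 hpi b, -11.44 without vector 8 dpi a and -5.68 without vector 8 dpi b. WBGene00255694.a fell by 3.73 (SE 0.54, -2.96 to -5.37 with a library left out, -1.78 with library size alone). miR-9 was called as a family (2 over the list alone, fry adjusted p = 0.000146), though WB_new_5.a stood at -2.26 without vector 18 hpi b and missed the threshold with library size alone (-0.88, adjusted p = 0.0551), where WB_new_4.a stood at -1.41. The call of miR-100/miR-51 (1 lower, 3 not called, fry adjusted p = 0.00261, 1 over the list alone) rested on 1 member. It ended without the 3 microRNAs largest over all libraries, a setting that kept miR-34 in the library sizes (0.063). It turned with library size alone (median 1.28, 0.79), as did miR-1 (-1.86, and 0.03 with library size alone). miR-86 rose by 2.14 (WBGene00235434.a, 4.09 with library size alone) from 4 to 138 counts, a call that ended without either 18 hpi library or vector 8 dpi b (1.84 to 2.19). Of 17 calls, 3 were higher and 14 lower (26 at an unadjusted p under 0.05); library size alone gave 19 and 6. Its median shift was 1.96 among the 52 arms with counts at both times, and 0.50 over all 135, of which 43 had 0 counts at both. In simulated libraries 22.7% to 36.8% of calls were false.

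The miR-100/miR-51 member WBGene00235495.a was already lower at 4 dpi than at 18 hpi (-2.23, SE 0.35, edgeR adjusted p = 5.87e-08, or -1.42 with RLE factors and -1.43 with library size alone). Of 3 calls, all lower (13 at an unadjusted p under 0.05), the other 2, miR-9 WB_new_4.a (-1.42) and miR-1 (-1.22), ended under every other scaling (-0.68 and -0.46 with RLE factors), and without vector 18 hpi b (-1.04, -1.08) or vector 4 dpi b (-1.03, -1.06). The miR-1 call also ended without vector 4 dpi a (-1.38). RLE factors gave 1 higher and 1 lower call, with a median shift of 0.76, and library size alone 3 and 1, with a median shift of 0.78 among the 52 arms with counts at both times. The family calls of miR-100/miR-51 and miR-9 (both fry adjusted p = 0.0349; 1 and 2 over the list alone) ended without vector 18 hpi b (0.413 for both), vector 4 dpi a (0.0786 and 0.0578) or vector 4 dpi b (0.337 for both), and under every other scaling. From 4 to 8 dpi miR-34 fell by 2.44 (SE 0.36) and WBGene00235495.a by 2.31 (SE 0.37), let-7 went from 17 counts to 1 (ratio 49.9, 7.83 to 2087). Its fitted change of -5.58, no bound, moved to -4.44 with library size alone, -10.41 without vector 8 dpi a and -4.66 without vector 8 dpi b. miR-92 rose by 2.07 (SE 0.39, 12110 ± 3107 to 50404 ± 5330.1 CPM) and miR-50/miR-190 by 2.05 (SE 0.47). lin-4 (WBGene00255642.a) rose from 39435 ± 1252 to 90739.6 ± 243 CPM (log2 2.38 with library size alone). The call ended with RLE factors (0.73) and without the 3 microRNAs largest over all libraries, which kept miR-34 in the library sizes (1.05). It also ended without vector 4 dpi a (1.23), vector 4 dpi b (1.17) or vector 8 dpi a. miR-86 rose by 2.38 (SE 0.53, 3.09 without vector 4 dpi a), a call that ended without vector 4 dpi b (1.85). Both miR-9 members were lower (WB_new_4.a -1.93, WB_new_5.a -1.81, fry adjusted p = 0.00557; 2 over the list alone), a family call that ended with library size alone (0.187) and without vector 4 dpi a (0.0598) or vector 8 dpi a (0.0646). The calls of both members ended with library size alone (WB_new_4.a -0.73, adjusted p 0.176; WB_new_5.a -0.62, 0.281). Of 13 calls 5 were higher and 8 lower (25 at an unadjusted p under 0.05); RLE factors gave 3 and 13 and library size alone 16 and 4, with median shifts of -0.46 and 1.13. With library size alone miR-34 WBGene00255665.a stood at -1.26, WBGene00235495.a at -1.18, miR-92 WBGene00255614.a at 3.25, miR-50/miR-190 WBGene00235460.a at 3.22 and miR-86 WBGene00235434.a at 3.55.

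Immature females at 24 dpi and immature males at 20 dpi differ in age as well as sex. Females held more WBGene00235425.b (chromosome 1, 5816924 to 5816947, minus strand, 2139.5 ± 406 against 519 ± 19.5 CPM; log2 2.04, SE 0.44, edgeR adjusted p = 9.97e-05, n = 2 each). Males held more WBGene00255698.b (chromosome 3, 2876892 to 2876912, plus strand, ACATATCGGTCCACGGGAAAG; -2.48, SE 0.42, adjusted p = 6.57e-07) and WBGene00255659.a (chromosome 2, 2820524 to 2820548, plus strand, -2.02, SE 0.43). WBGene00255614.b, the other arm of miR-92, had 3 counts in females and 27 in males, a ratio of 15.9 (4.91 to 82.1). Its fitted change of -3.81 moved to -4.50 without immature female a. miR-87 WBGene00255662.a was higher in females (2.20, SE 0.50), as were miR-200/miR-236 (2.52, SE 0.67) and bantam WB_new_29.a (1.65, SE 0.39), but none held with every library left out. The miR-87 call ended without immature male b (1.91). The miR-200/miR-236 call ended without immature male a (2.06) or immature female a (1.81), and stood at 3.83 without immature male b. The bantam call ended without immature male a (1.28) or immature female a (0.94). In males miR-71 (-1.41), miR-92 (-1.54) and let-7 (-1.30) were higher, calls that ended without immature male a (-0.98, -0.86 and -1.07) and, for miR-71 and let-7, without immature female b (-1.33 and -0.95). lin-4 was not called (-0.39). The bantam and miR-87 families were each called with a fry adjusted p of 0.0345 (1 over each list alone) and lost without immature male a, immature male b or immature female a (highest 0.374) and without the 3 largest microRNAs in the library sizes (0.0501 each). miR-2/miR-43 was called only in the mixed test (0.0386; 1 over the list alone), and its called member WBGene00235522.a (1.77) ended without immature male a (1.62) or immature female a (1.04). In all 24 arms were called, 7 higher and 17 lower (40 at an unadjusted p under 0.05); library size alone gave 19 and 12, with a median shift of 0.29, and leaving out the vector libraries 19 and 10.

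Adult and immature females were compared next. Adult females carry embryos, so maturation of the worm and the presence of embryos were not separated. Adults held WBGene00255629.b at least 790-fold higher, WB_new_1.b (chromosome 2, 11909512 to 11909532, plus strand, AGTTGTATCGGCTGTGATATG) at least 462-fold, and WB_new_7.a and WB_new_6.a, 2 copies of CGGGATAGTCTCTCACGGTAGAGC, at least 349-fold and 326-fold, all with 0 counts in immature females. In isolated embryos these 4 stood near the adult females (log2 -0.12, 0.17, 0.63 and 0.64 in the same order, not called). miR-2/miR-43 was called higher as a family, with 7 of 10 members higher, 2 lower and 1 not called (9 over the list alone, fry adjusted p = 2.10e-08). The median log2 was 5.93, and 6.70 without immature female a. Copies of a sequence count separately here too, and the family's share of counts was 7.22 ± 1.35% in adults and 4.59 ± 0.04% in immature females. Of the lower members, WBGene00235522.a (-1.58) ended without immature female a (-0.88). miR-35/miR-36 was higher in both members (2 over the list alone, fry adjusted p = 1.73e-05; median log2 6.76, or 5.52 with bounds; 7.49 without immature female a), with WBGene00255671.b at least 33.5-fold higher. miR-7 rose by 3.43 (SE 0.46), miR-44/miR-279 WBGene00255646.a by 2.12 (SE 0.35) and miR-100/miR-51 WBGene00255697.a by 1.97 (SE 0.31, 2.59 without immature female b). The last family was called higher (2 over the list alone, fry adjusted p = 0.0022). lin-4 fell by 3.42 (SE 0.28, 44989.9 ± 7472 to 4184 ± 469 CPM, adjusted p = 2.10e-31), let-7 by 2.04, miR-252 (WBGene00235400.a) by 2.13 (SE 0.46), miR-71 by 1.23 and miR-2/miR-43 WBGene00255680.a by 1.80 (SE 0.27).

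Both miR-9 members fell (-1.39 and -1.40; 2 over the list alone, fry adjusted p = 0.0012), and miR-4/miR-79 was lower as a family (1 of 2 called, 1 over the list alone, 0.00305), through WB_new_4.b (-1.99; -2.63 without adult female c). WBGene00235416.b (X chromosome, 461977 to 461998, minus strand) fell by 3.45 (SE 0.50), with an opposite-strand partner of equal counts. bantam was called lower (2 over the list alone, 0.00498) but not with library size alone (0.0778), without immature female a (0.171) or without adult female a (0.0669). Its member WB_new_29.a (-0.90) ended with RLE factors (-0.40), with library size alone (-0.50) and without immature female a (-0.23), adult female a (-0.68) or adult female d (-0.62). Its member WBGene00235433.a (-0.68) ended under every other scaling (-0.26 with RLE factors, -0.38 with library size alone, -0.52 without the 3 largest) and without immature female a (-0.33) or adult female a (-0.44), b (-0.47) or c (-0.45). miR-44/miR-279 was called higher at 0.0499 with 1 member higher and WBGene00235521.a lower at -0.74 (2 over the list alone), but not without immature female b (0.622). The call of WBGene00235521.a ended under every other scaling (-0.26 with RLE factors, -0.36 with library size alone) and in 5 of the 6 left-out libraries (-0.14 without immature female a). In all, 99 arms were called, 56 higher and 43 lower (104 at an unadjusted p under 0.05); RLE factors gave 64 and 28 and library size alone 63 and 30, with median shifts of 0.42 and 0.32.

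Adult and immature males were compared in the same way. The miR-2/miR-43 member WBGene00255649.a (chromosome 2, 11612227 to 11612249, plus strand, TATCACAGTACTATTCCGGGCAT) rose by 7.28 (SE 0.51, 154 ± 60.4 to 22349 ± 654 CPM, n = 2 each, edgeR adjusted p = 6.49e-42), and the other arm of its gene, WBGene00255649.b (ACCTGAATTGAATTGTGATATG), was at least 57.7-fold higher. WB_new_30.a rose by 3.97 (SE 0.54; contig Bm_289, 2157 to 2178, minus strand; its opposite-strand partner WB_new_31.b has equal counts) and miR-34 by 2.10 (SE 0.37, 4349 ± 193 to 18672 ± 87.6 CPM). miR-71 (WBGene00235458.a) fell by 2.38 (SE 0.36, -1.77 with RLE factors, 394030 ± 162654 to 75775 ± 1151 CPM) and WBGene00235425.a, an arm of the gene whose other arm differed between the immature sexes, by 3.25. let-7 (WBGene00233297.a) was not called (0.80, adjusted p = 0.0552), but was called higher with RLE factors (1.41), library size alone (1.28) and without the 3 largest microRNAs in the library sizes (0.95). miR-44/miR-279 WBGene00255646.a rose by 1.49 (1.43, adjusted p = 0.0628, without immature male b). miR-2/miR-43 was called higher with 1 of 10 members called (1 over the list alone, fry adjusted p = 0.00716; median log2 1.45), but not without immature male b (0.83, 0.133), and its median was 0.70 without adult male a. bantam (2 of 2 lower; 2 over the list alone, 0.00716) was lost without immature male b (0.0669) or adult male b (0.143) and with library size alone (0.088). Its member WBGene00235433.a (-0.83) ended under every other scaling (-0.24 with RLE factors, -0.37 with library size alone, -0.69 without the 3 largest) and without any 1 of the 4 libraries (-0.68 to -0.93). Its member WB_new_29.a (-1.43) ended with RLE factors (-0.87) and without immature male b (-0.99) or adult male b (-1.14). miR-4/miR-79 (1 of 2 lower; 1 over the list alone, 0.014) was lost without immature male a (0.0813), adult male a (0.136) or adult male b (0.0951), with RLE factors (0.0798) and with library size alone (0.055). The call of its member WBGene00235393.a (-2.75) ended with RLE factors (-2.20) and without the same libraries (-2.47 to -2.71). In all, 43 arms were called, 22 higher and 21 lower (56 at an unadjusted p under 0.05); RLE factors gave 39 and 7, library size alone 35 and 11, and leaving out the vector libraries 40 and 4, with median shifts of 0.56 and 0.40 for the first pair.

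Whether the sex difference changes with maturity was tested as an interaction. The immature sexes also differ in age and adult females carry embryos, so the interaction cannot be told apart from these. The female-minus-male difference was more negative in adults for let-7 (-2.84, SE 0.46), lin-4 (-2.26, SE 0.44, -2.96 without immature male a) and miR-2/miR-43 WBGene00255649.a (-3.57, SE 0.62), and more positive for miR-7 (4.36, SE 0.76), miR-100/miR-51 WBGene00255697.a (2.34, SE 0.46, 2.99 without immature female b) and miR-2/miR-43 WB_new_2.a (8.38, SE 1.52, 7.39 to 10.7 with a library left out). In all 54 of 135 arms differed, 33 more positive and 21 more negative (edgeR quasi-likelihood, Benjamini-Hochberg; 60 at an unadjusted p under 0.05), and 23 and 28 without the vector libraries. miR-2/miR-43 was called in the mixed test (fry adjusted p = 1.21e-06; 6 over the list alone) and not in a single direction (0.595).

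Of the other listed families, miR-124 was measured with 12 counts in all and not tested, and miR-10, miR-133 and miR-184 had 0 measured members. The 57 named arms of the main comparisons had predicted sites in 477 to 6478 transcripts each (median 2233), and in 339 to 6067 (median 1966) with alignments of at least 15 bases.

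The deposited mRNA table was described without a test. Its 5918 genes fall into 5 modules, of which tan is the largest with 3454 genes. The 2569 tan genes that are not inverted had a median z of 1.34 in embryos, 0.95 in adult females, -0.44 in adult males and -0.72 to -0.95 in the jird stages. The 1195 such genes of the black module stood highest in adult males (2.38), and the 158 of the magenta module in jird larvae at 4 dpi (2.37). In the authors' deposited table, the tan genes that are not inverted held 62 of the 130 genes with an RNA recognition motif (odds ratio 4.39, corrected p = 8.11e-11), 40 of 74 with a helicase ATP-binding domain (5.62) and 361 of 1268 annotated with protein binding (2.07).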

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

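All the tests of explanations in this part were chosen only after the results they measure were seen, whereas the test of the sex difference was planned.

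The sex difference of 54 of the 135 microRNAs differed between adult and immature worms (edgeR quasi-likelihood, Benjamini-Hochberg). Age of the immature sexes and embryos inside adult females were not separated from it. The most negative log2 differences, adults minus immature worms, were WBGene00255649.b at -5.22 (SE 1.77; adjusted p 0.153 without immature male b), WBGene00255689.a at -4.07 (SE 1.33; -3.45 without immature male a and -8.12 without b), WBGene00255666.a at -4.01 (SE 0.45; -3.11 without immature female a) and WB_new_14.a at -3.80 (SE 1.43; adjusted p 0.0889 without immature male b and 0.0582 without adult male a). WBGene00255649.b also missed the threshold without immature female a (adjusted p 0.0553) and without adult male b (0.0503). The most positive were WB_new_6.a at 9.99 (7.07 and no longer called without immature male b; 14.0 without adult male b and 8.98 without a), WB_new_11.a at 10.40 (13.3 without adult male a and 9.63 without b), WB_new_22.a at 10.80 (8.71 and no longer called without immature male a and 12.2 without b) and WBGene00255629.b at 12.73 (11.8 without adult male a and 15.8 without b; 11.9 and 13.7 without immature male a and b). The last 4 had 0 counts in immature females and 3 or fewer in adult males, so their fitted values are no bound.

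WBGene00235516.b, the other arm of the miR-200/miR-236 gene, stood at 123 CPM in adult female a, far from the other 3 libraries (0, 18.9 and 19.7). This is 1 of 49 values tested for a library apart from its group, and chance gives about 1 in 20.

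miR-34 took 23.9% to 63.6% of counts in the 6 vector libraries and 0.252% to 2.51% in the other 15. Counting error in shallow libraries alone does not account for it. The lowest 95% bound of a vector library, 22.7%, lies above the highest of the others, 2.71%. These bounds cover counting error only, and other effects of shallow libraries were not tested. Reads from mosquito RNA may contribute: 4 of the 8 tested microRNAs whose sequence insects share, a list written after the values were seen that holds miR-34 itself, were lower at 8 dpi in jirds, against 4 of the other 127 (one-sided Fisher exact p = 0.000335), while without miR-34 it was 3 of 7 (exact p = 0.00285) and 2 of these, let-7 and miR-71, were higher. The stage of the larvae stays open too, with a log2 change of -5.61 between 8 dpi in the vector and in jirds. Host and stage change together and there is no library of mosquito alone, so the pair cannot be told apart.

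Of the 49 microRNAs higher in adult females than in males, which carry 37 distinct sequences, embryos inside the females are a candidate explanation. Of 3 that were lower in isolated embryos than in females, 2 lay beyond the largest scaling shift of 0.387 and 2 standard errors, WB_new_28.a and bantam WB_new_29.a. The second was not called with limma on log2(TPM + 1) (-1.43). Their levels argue against embryos as the whole cause only if the isolated embryos match those inside the females, which the labels do not say. The explanation stays open for 1 within that margin, WB_new_11.a (-0.98, SE 0.37). For the other 46, with a median log2 change of 0.28 from females to embryos (10 called higher, 36 not called), it cannot be told apart from sex, which was not tested separately. Reads shared between copies were not tested directly. WBGene00255629.a, WB_new_1.a, WB_new_2.a and WB_new_3.a, copies of a single sequence, held near-equal counts in females (1500, 1497, 1464 and 1510). Reads split between identical sequences would give this, so folds of single copies are not separate results. With the copies of a sequence summed, 41 were higher, but summing copies that move alike could not have ended a call.

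Neighbouring genes tended to be called in the same direction between females and males, in 30 of 38 pairs within 10 kb (mean of shuffles 6.70; permutation p = 1e-05, the smallest that 100000 shuffles can give). This p restates the chromosome 2 stretch and the contig Bm_034_hap, which had been seen before the test. Without them 2 of 10 pairs did (mean 1.47; permutation p = 0.396), which gives no support elsewhere. Genes with the same main sequence, and opposite-strand partners, had been reduced to 1 gene each before this test, which left 73 genes. Whether shared genomic position applies to those clusters stays open, because they had prompted the test.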

How the results depend on the processing

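The settings with a single arm kept of each opposite-strand pair, without the vector libraries and without insect-shared sequences were chosen after seeing the data. Of the named microRNA values, RLE factors left 207 on the same side of the threshold and weakened 29, library size alone 199 and 35 with 2 reversed, DESeq2 200 and 35, and no filter on low counts 195 and 41; limma on log2(TPM + 1) left 113 and weakened 65. Leaving out a library at a time left 1037 and weakened 291. Library size alone reversed miR-1 WB_new_27.a (0.032), miR-71 WBGene00235458.a (0.53) and the miR-100/miR-51 family (1.28) in vector 8 dpi vs vector 18 hpi, and the mean of 4 dpi and 8 dpi stages reversed miR-50/miR-190 WBGene00235460.a (0.27) in jird 8 dpi vs vector 8 dpi; the cause was not tested.

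Counts of calls moved by more than 1.5 times in the settings below. A range over left-out libraries can also hold counts that moved less. The 3 largest microRNAs are those over all libraries, which keeps miR-34 in the library sizes of the vector. Embryos vs adult females gave 22 with limma on log2(TPM + 1) and 17 to 33 with a library left out. Jird 8 dpi vs vector 8 dpi gave 20 with RLE factors, 21 with library size alone, 19 with the copies of a sequence summed, 19 without insect-shared sequences and 15 to 30 with a library left out. Vector 8 dpi vs vector 18 hpi gave 9 without insect-shared sequences and 11 to 16 with a library left out. Vector 4 dpi vs vector 18 hpi gave 1 without the 3 largest microRNAs in the library sizes, 1 with no filter, 1 with copies summed, 1 with DESeq2, 1 with a single arm of each opposite-strand pair and 1 to 5 with a library left out. Vector 8 dpi vs vector 4 dpi gave 20 with library size alone and 8 without insect-shared sequences. Immature female vs immature male gave 9 with only the groups compared, 11, 11 and 13 with limma on log2(TPM + 1), log2(TPM + 10) and TPM of 10 or more, and 6 to 18 with a library left out. Adult male vs immature male gave 22 to 31 with a library left out. The cause was not tested, though dropping a library or microRNAs leaves fewer to test. Where a group is left with a single library, that library is assumed to vary like the other groups.

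Replicate letters did not pair the libraries (36 pairs of groups, r -0.28 to 0.23), and a block on them gave 79 calls between adult females and males and 35 between embryos and females. TPM values do not cover the vector libraries, so those settings have no value there. Not run were a stricter target score, families by name and alternatives for the mRNA table. The 1820 to 5348 counts of the vector libraries limit what can be called there.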

Other observations

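The microRNAs of this part were chosen after their values were seen. The miR-31/miR-72 arm WBGene00255695.a stood at 401 ± 210 CPM in adult females (n = 4) and 886 ± 135 in immature females (n = 2), a log2 change of -1.15 (SE 0.37; edgeR adjusted p = 0.00284); the call ended without adult female c (-0.71) or immature female b (adjusted p = 0.0525) and with RLE factors (-0.73). miR-993 (WBGene00235659.a) was higher in jird larvae than in vector larvae at 8 dpi (adjusted p = 0.000185), a call that ended without jird 8 dpi b (1.01), with RLE factors (0.72, adjusted p = 0.0945) and with library size alone (0.55, 0.279).

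Between adult females and males, 7 of 30 tested arms on the X chromosome were higher in females, against 42 of 105 elsewhere (two-sided Fisher exact p = 0.131), and 4 of 30 against 27 of 105 were lower (exact p = 0.219). The split depends on the chromosome 2 stretch and the contig Bm_034_hap. Without them it was 7 of 30 against 15 of 77 higher (exact p = 0.790) and 4 of 30 against 27 of 77 lower (exact p = 0.0325), so no conclusion about the X chromosome is drawn.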
